A study of Sus scrofa with 9 samples.

How the data were processed

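Skeletal muscle RNA of Bama minipigs, a small Chinese pig breed used as a model of obesity, was measured on 9 Agilent porcine expression arrays with a single dye. Per the labels, the muscle was longissimus dorsi, total RNA was extracted with TRIzol and purified on columns with DNase, and the RNA was amplified and labelled with Cy3 by a low-input kit. The labels place 6 animals in the high-fat high-sucrose diet group (HFHSD) and 3 in the control diet group (CD), with 1 array per animal. The descriptions differ on the number of CD animals: the series design gives 3 and the growth protocol 6. Only 3 CD arrays are in the series. Replicate numbers were given here in accession order and only name the arrays.

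The deposited scanner files hold spot intensity values on a linear scale. Per the file headers, the authors extracted them with Agilent Feature Extraction 10.7.3.1, whose processed signal is background-subtracted and detrended within each array and is not scaled between arrays. The deposited table of the whole series holds the same processed intensity values: 0 spots differed on each of the 9 arrays, so its scale is linear and uncentred, and its medians ranged from 13.0 on CD 1 to 40.0 on HFHSD 6. No other per-sample columns were used.

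Control spots and spots marked as outliers were left out, and spots of the same probe were averaged on the log2 scale. Of 43603 probes, 22 were dropped because every spot on some array was marked as an outlier. The log2 of the processed signal minus the array's 75th percentile was the working value, so a value of 0 is the 75th percentile of that array. Probes were tested if they were well above background, by the scanner software's own call, on at least 3 arrays, which left 27922 probes.

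Array files carry an accession for each probe and no gene symbol. Accessions were matched, without versions, to a RefSeq gene table of the Sscrofa11.1 assembly, which was used for names only, and no coordinates are given because the array files name no genome build. This named 6891 probes of 3196 genes and left 36712 probes unnamed, among them 6818 with an Ensembl transcript name and 12909 with a transcript cluster name. The arrays carry an older and a newer annotation of the same probes: 6874 probes were named through the newer one and 17 only through the older one, and 2 probes with different genes in each stayed unnamed. A gene with several probes is represented by its brightest probe, which gave 2613 tested genes.

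The diets were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes, two-sided, over all 9 arrays and without covariates. P-values were adjusted by the Benjamini-Hochberg method over all tested probes, with a threshold of 0.05. Differences are HFHSD minus CD in log2, with the standard error (SE) of the limma fit, and levels are means with the standard deviation (SD) between arrays. Each array is a separate animal, so these spreads include the variation between animals.

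Gene lists of pathways and cell types were fixed before the data were examined, 34 in all, and 31 had at least 5 measured genes. Lists were tested with camera, with a preset correlation of 0.01 between genes and adjustment over the 31 lists. Beside it stand camera with an estimated correlation, fry, an exact two-sided permutation test of the list mean over all 84 splits of the arrays into 6 and 3, and the number of members that pass when adjusted over the list alone. The smallest p the permutation test can give is 0.0119. Camera compares a list with the other genes, whereas fry asks only whether the list's own members changed. The circadian clock list had 1 measured gene and the list of erythrocyte and blood plasma genes had 4, so neither was tested, and the list of sex-linked transcripts had 0.

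The genes named in the text follow a rule that was fixed at the same time. They are the 10 genes with the largest called difference in each direction whose groups do not overlap, up to 4 members of each list with the smallest p, and a panel of 26 genes of lipid storage and muscle growth, of which 25 were measured; TRIM63 had no named probe. Genes outside this rule are marked as chosen after their values were seen.

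The arrays came from 3 slides, numbered here. Slide 1 held HFHSD 5 and HFHSD 6 and was scanned on a different day from the others, slide 2 held HFHSD 1, HFHSD 3, HFHSD 4 and CD 1, and slide 3 held HFHSD 2, CD 2 and CD 3. Slide was left out of the model and entered as an alternative, as a fixed and as a random block. The share of probes well above background ran from 51.2% to 68.9% on 8 arrays and was 36.8% on CD 1. Its negative controls had an SD of 5.66, the highest of the arrays, against 1.67 on HFHSD 5, the lowest. The number of arrays limits the precision.

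Other alternatives were quantile normalisation, normexp background correction with an offset of 50 followed by either scaling, other filters on dim probes, array weights, a variance trend with a robust prior, other thresholds, the mean of a gene's probes, and leaving out each array in turn. The array files hold median and no mean foreground signals, so normexp ran on the median foreground and background intensity, which departs from the plan. The procedure was tested on simulated data with the means and spreads of the 27922 probes, in which 200 probes were changed, over 5 runs of the comparison of HFHSD with CD. Of probes changed by a log2 difference of 1, 17.9% were recovered, of those changed by 2, 65.8%, and of those changed by 3, 77.3%, while 4.96% of the called probes were false. The simulated noise was independent between probes and arrays and held no differences between slides. These shares therefore do not cover errors that come from the slides.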

Results

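Muscle transcript levels were compared between Bama minipigs fed a high-fat high-sucrose diet and minipigs fed standard chow. The diet of the HFHSD group was 53% basal feed, 37% sucrose and 10% lard, and it was given for 23 months from an age of 6 months. The series title names lipid deposition and the inhibition of skeletal muscle growth as its subject. Both sexes were used, per the labels, which do not give the sex of each animal. Longissimus dorsi of 6 HFHSD animals and 3 CD animals was measured, 1 array per animal.

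The diet comparison addresses which transcripts differ in muscle after long feeding. MYOC, a secreted glycoprotein of muscle and eye, rose by a log2 difference of 2.36 (SE 0.22, adjusted p = 0.00251), from 2.08 ± 0.27 (SD, n = 3) in CD to 4.44 ± 0.28 (SD, n = 6) in HFHSD, and all 3 of its probes passed. ALDOC, an aldolase of glycolysis, rose by 2.22 (SE 0.45, adjusted p = 0.0489; 0.135 with slide as a fixed block), and APOE, a carrier of lipids, by 1.85 (SE 0.36, adjusted p = 0.0455), which shrank to 0.40 with normexp and percentile scaling and did not pass with slide as a fixed block (adjusted p = 0.129). CIDEA, a lipid droplet protein of adipocytes, rose by 1.49 (SE 0.28, adjusted p = 0.0378, and 0.0886 with slide as a fixed block). MUL1, a ubiquitin ligase of the mitochondrial outer membrane measured by 1 probe, had the largest difference of any named gene: it was 2.94 ± 0.49 (SD, n = 3) in CD and -1.64 ± 0.37 (SD, n = 6) in HFHSD, a difference of -4.58 (SE 0.28, adjusted p = 1.3e-04).

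Other genes that rose were METTL11B (1.86), BMPR1B, a receptor of bone morphogenetic proteins (1.52), KCNN3, a calcium-activated potassium channel (1.43), EGF, a growth factor (1.30), and TIGD4 (1.27). In the setting of normexp and percentile scaling METTL11B shrank to 0.34, KCNN3 to 0.49, TIGD4 to 0.55 and BMPR1B to 0.73. DMP1 rose by 1.37, a direction that turned to -0.019 with normexp and percentile scaling. METTL11B, KCNN3, DMP1 and also APOE were well above background on 2 of 3 CD arrays and on 6 of 6 HFHSD arrays. Their CD means thus include a value near or under the background. CAT, the catalase that breaks down hydrogen peroxide, rose by 0.80 (adjusted p = 0.0401), from 4.53 ± 0.068 (SD, n = 3) to 5.33 ± 0.081 (SD, n = 6). SLA-DQB1, a class II antigen-presenting chain, rose by 0.93 (adjusted p = 0.0371). All their probes were higher, but only 1 of 9 CAT probes and 1 of 4 SLA-DQB1 probes passed. Each of the 2 genes passed in 8 of 23 alternatives. FCGR3A, an immunoglobulin receptor, rose by 1.19 and was chosen after its values were seen.

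Among the genes that fell, EPHX1, an epoxide hydrolase, changed by -2.57 (SE 0.36, adjusted p = 0.0161) and TBC1D20, an activator of Rab GTPases, by -1.91 (SE 0.31, adjusted p = 0.0255). SLC25A6, which exchanges ADP and ATP across the inner mitochondrial membrane, fell from 7.63 ± 0.17 (SD, n = 3) to 6.24 ± 0.17 (SD, n = 6), a change of -1.39 (SE 0.18, adjusted p = 0.0141), and all 6 of its probes passed. The nuclear receptor NR6A1 changed by -1.66 and the coactivator NCOA3 by -1.62, which shrank to -0.82 and -0.76 with normexp and percentile scaling and to -0.49 and -0.36 with normexp and quantile normalisation. NCOA3 was well above background on 3 of 6 HFHSD arrays, and 2 of its 4 probes passed, with the weakest probe at -0.21. TNFRSF1A, a receptor of tumour necrosis factor, changed by -1.40, with 1 of its 3 probes passing and the weakest at -0.62. SLPI, an inhibitor of leukocyte proteases, changed by -1.38, with all 7 of its probes lower and 1 passing. The thioredoxin reductase TXNRD1 changed by -1.28 and POPDC3 by -1.17. DPM1 (-1.13) and PDXK (-1.06) also fell and were chosen after their values were seen; 1 of the 3 probes of DPM1 went the other way, at 0.22, without passing. With normexp and percentile scaling DPM1 was -0.72 and PDXK -0.66, and with the mean of its probes DPM1 was -0.31.

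In all, 344 of 27922 probes passed, 194 higher and 150 lower in HFHSD, and 4599 had an unadjusted p under 0.05. The HFHSD and CD arrays did not overlap for any of the 344 probes; over all tested probes they did not overlap for 3047, where chance gives 2.38%. Of the 344 probes, 61 had a gene name. They belonged to 41 genes, and 26 genes passed by their brightest probe, 13 in each direction. With slide as a fixed block 84 probes and 7 genes passed, and of the 26 genes only MUL1, MYOC, SLC25A6, DMP1 and DPM1 were among them. MUL1 differed by -4.78 within slide 2 and by -4.34 within slide 3. The count was 99 without HFHSD 2, 75 without HFHSD 3, 161 without HFHSD 5, 93 without HFHSD 6, 32 without CD 1, 87 without CD 2 and 25 without CD 3, and MUL1 alone of the 26 genes passed in all 23 alternatives.

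**Figure D1:**
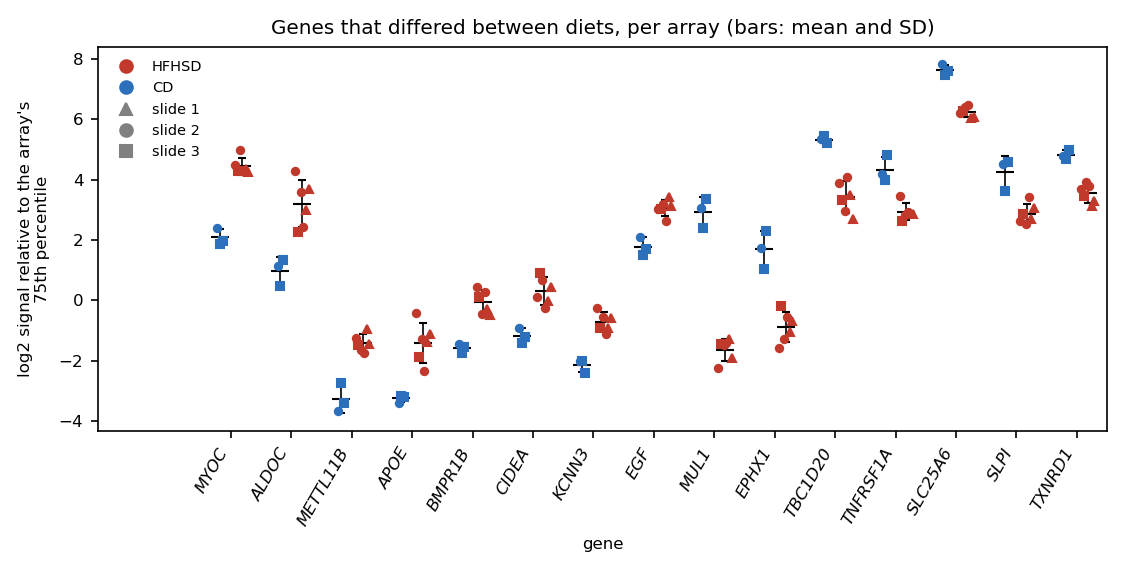
Log2 signal relative to each array's 75th percentile (y axis) for 15 genes that differed between diets (x axis), with 1 point per array, coloured by diet and shaped by slide, and bars for the mean and SD of each group. For MUL1 the HFHSD arrays lie between -2.24 and -1.29 and the CD arrays between 2.40 and 3.36.

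Of the adipocyte list, 18 of 24 genes were measured, 12 of them higher in HFHSD, with a median log2 difference of 0.33 and a mean of 0.48. By the brightest probe only CIDEA passed over all probes, and a dimmer probe of TUSC5 also passed. Adjusted over the list alone, 4 members passed: CIDEA, ADIPOQ, CIDEC and PPARG. ADIPOQ, the hormone adiponectin, differed by 2.47 (SE 0.71, adjusted p = 0.113) and ranged in HFHSD from -0.94 to 2.58. CIDEC differed by 2.06 (adjusted p = 0.115; 0.47 with normexp and percentile scaling) and PPARG, the main regulator of fat cell differentiation, by 0.96 (adjusted p = 0.119). FABP4, a fatty acid carrier, differed by 0.32, LEP, which encodes leptin, by 1.01, and LIPE by 1.20. LEP shrank to 0.092 with normexp and percentile scaling, and without CD 1 LEP was 0.38 and FABP4 0.13. PLIN1 was not well above background on any CD array and was measured on 5 of 6 HFHSD arrays. The list did not pass with camera (adjusted p = 0.0668, adjusted p = 0.698 with an estimated correlation), whereas fry's test for change in either direction gave an adjusted p of 0.00318. With camera it passed as higher in 4 of 24 alternatives. These were no filter on dim probes (adjusted p = 0.0447), without HFHSD 3 (0.0477), without HFHSD 4 (0.0119) and the mean of a gene's probes (0.0176). The list mean differed by 0.22 within slide 2 and 0.51 within slide 3.

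Of the fatty acid and triglyceride synthesis list, 12 of 21 genes were measured, 6 in each direction, and 0 passed over all probes by their brightest probe. Adjusted over the list alone, 3 were higher and 3 lower. SCD, the desaturase that makes monounsaturated fatty acids, differed by 2.43 by its brightest probe (SE 0.55, adjusted p = 0.0652), all 8 of its probes were higher, and 1 other probe passed at 3.04. DGAT2, which completes triglyceride synthesis, differed by 1.47 (adjusted p = 0.0744) and by 0.37 with normexp and percentile scaling, while DGAT1 differed by -0.72 (adjusted p = 0.0899) and AGPAT2 by -0.94 (adjusted p = 0.0919). FASN differed by 0.52 (adjusted p = 0.678). PNPLA3, chosen after its values were seen, differed by 3.48 (adjusted p = 0.0993). The list's median was -0.13 and turned to 0.18 with normexp and percentile scaling, its mean was 0.39 and its camera direction higher (adjusted p = 0.732). Of the list for fatty acid uptake and lipid droplets of muscle, 18 genes were measured, 9 in each direction, with a median of -0.063 that turned to 0.16 with normexp and percentile scaling, and 0 passed (camera adjusted p = 0.918). The fatty acid transporter CD36 differed by 0.035 and LPL, which frees fatty acids from lipoproteins, by 0.12, and both signs turned when single arrays were left out. FITM2 differed by -1.55 (adjusted p = 0.0901). Cholesterol synthesis and uptake, with 7 measured genes, had a median of -0.34 (adjusted p = 0.739).

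The muscle growth genes did not pass over all probes. MSTN, which encodes myostatin, an inhibitor of muscle growth, differed by 1.35 (SE 0.32, adjusted p = 0.0759) and by 0.37 with normexp and percentile scaling, with 2 of 3 CD arrays and 6 of 6 HFHSD arrays well above background. MYOD1, a regulator of the myogenic programme, differed by -1.93 (SE 0.49, adjusted p = 0.0863), measured on 2 of 3 CD and 3 of 6 HFHSD arrays. Adjusted over the list alone, MSTN passed in the list of muscle growth inhibition and TGF-beta family (16 measured, median 0.080 but -0.13 with normexp and percentile scaling, camera adjusted p = 0.488), and MYOD1 and VCAM1 passed, in opposite directions, in the list of myogenesis and satellite cells (15 measured, median 0.097, camera adjusted p = 0.521). The latter list passed as higher with normexp and percentile scaling (median 0.35, adjusted p = 0.0209), and fry's test for change in either direction gave it an adjusted p of 2.5e-07. VCAM1, an adhesion molecule also made by satellite cells, differed by 0.99 (adjusted p = 0.0577). MYOG differed by -0.26, which turned to 0.0071 with normexp and percentile scaling, IGF1 by -0.52 and IGF2 by 0.15. The list of atrophy, ubiquitin ligases and autophagy had 10 of 11 measured members lower, with a median of -0.35 that turned to 0.079 with normexp and percentile scaling, and did not pass (adjusted p = 0.137). FBXO32, a ubiquitin ligase of atrophy, differed by -0.59 and KLF15 by -1.15.

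Neither contractile list passed. Of the fast fibre list, 15 genes were measured, with a median of -0.087, and of the slow fibre list 11, with a median of -0.022, a mean of -0.24 and a camera direction of higher (adjusted p = 0.732 and 0.890), and both medians turned, to 0.37 and 0.43, with normexp and percentile scaling, where the fast fibre list passed as higher (adjusted p = 0.0128). The slow fibre mean differed by -0.70 within slide 2 and by 1.11 within slide 3. MYH2, the myosin of fast oxidative fibres, differed by -0.996 (adjusted p = 0.158), MYH4 by 0.61, MYH7, the slow myosin, by -0.22, and MYH1 by 0.014, of which MYH7 turned to 0.33 with normexp and percentile scaling and MYH1 turned to -0.11 with slide as a fixed block. TNNT3 differed by -1.04 (adjusted p = 0.108), and for MYH2 and TNNT3 the HFHSD and CD arrays did not overlap. Calcium handling and excitation had a median of 0.028 over 11 genes (adjusted p = 0.478), and it passed as higher with normexp and percentile scaling (median 0.57, adjusted p = 9.2e-04).

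**Figure D2:**
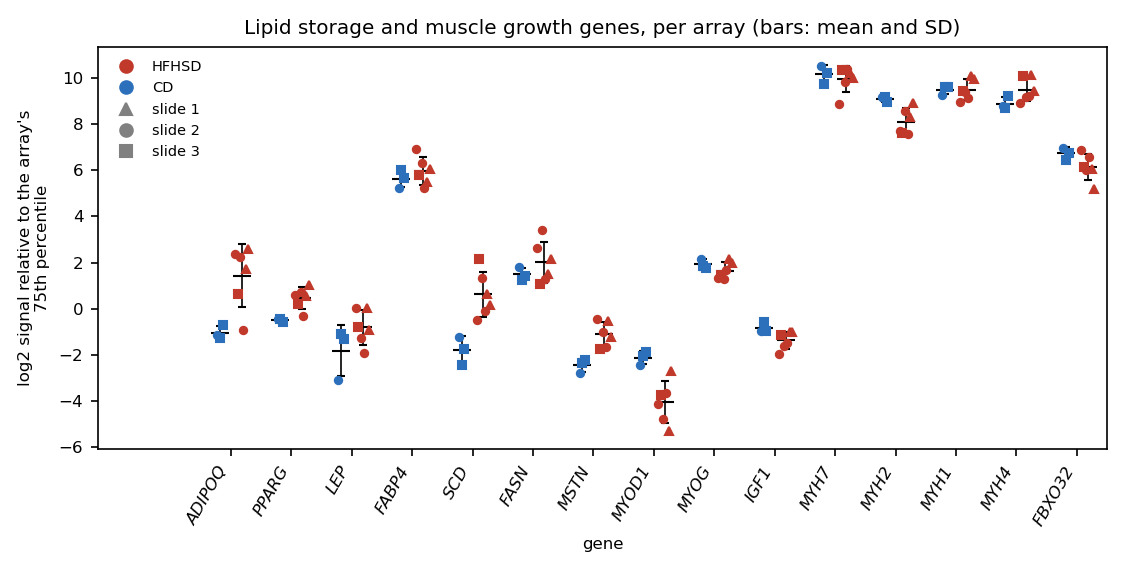
Log2 signal relative to each array's 75th percentile (y axis) for 15 genes of lipid storage and muscle growth (x axis), with 1 point per array, coloured by diet and shaped by slide, and bars for the mean and SD of each group. None of these genes passed by the brightest probe, and ADIPOQ ranged from -0.94 to 2.58 across the HFHSD arrays.

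Both lists that passed were of mitochondrial energy metabolism. All 16 measured oxidative phosphorylation genes were lower in HFHSD, with a median log2 difference of -0.35, and 10 of 11 measured tricarboxylic acid cycle genes were lower, with a median of -0.45 (camera adjusted p = 0.0323 for each, adjusted p = 0.887 for each with an estimated correlation), but the former median turned to 0.10 and the latter shrank to -0.022 with normexp and percentile scaling. Each list passed in 9 of 24 alternatives. Among these, the deposited value table and the variance trend, which does not enter camera, could only repeat the main result (camera adjusted p = 0.0323). No member passed over all probes by its brightest probe, though a dimmer probe of CYCS, an oxidative phosphorylation gene, did. Adjusted over the list alone, 0 oxidative phosphorylation genes and 1 tricarboxylic acid cycle gene passed. That gene was CS, the citrate synthase that opens the cycle, at -0.79 (SE 0.20, adjusted p = 0.0825). COX5B differed by -0.63, ATP5L by -0.67, ATP5G1 by -0.69, COX7A1 by -0.47, MDH2 by -0.61 and SUCLG1 by -0.41, the last of which turned to 0.0095 with normexp and percentile scaling. The exact permutation p of the list mean was 0.0714 for oxidative phosphorylation and 0.0238 for the tricarboxylic acid cycle. After adjustment 0 of 31 lists passed, but a single list at the smallest possible p of 0.0119 could not pass either. The fibroblast and fibro-adipogenic progenitor list was at that p, and its adjusted permutation p was 0.246. That 0 of 31 lists passed therefore says little about these lists. The means of the oxidative phosphorylation and tricarboxylic acid cycle lists differed by -0.43 and -0.55 within slide 2 and by -0.046 and -0.12 within slide 3. CD 1 was the only CD array of slide 2, and HFHSD 2 the only HFHSD array of slide 3. With slide as a fixed block the medians were -0.26 and -0.45, and neither list passed (adjusted p = 0.232 and 0.143).

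Other metabolic lists did not pass with camera, while fry's test for change in either direction passed for 8 lists, among them fatty acid and triglyceride synthesis (adjusted p = 1.5e-05), insulin and growth factor signalling (7.6e-05), glycolysis and glycogen (0.0103), inflammatory cytokines (0.0124) and the tricarboxylic acid cycle (0.0354). Fry's test for a shared direction passed for 0 of 31 lists, with an adjusted p of 0.236 for each list that passed with camera and 0.935 for fatty acid and triglyceride synthesis. Since 4599 of 27922 probes had an unadjusted p under 0.05, a pass of fry need not be particular to a list. Mitochondrial fatty acid oxidation had a median of -0.17 over 20 genes, which turned to 0.14 with normexp and percentile scaling (adjusted p = 0.732), with ACADM at 0.67, UCP3 at -0.88 and PDK4 at -0.79. Glycolysis and glycogen had 12 of 17 genes lower and a median of -0.36, which was -0.17 without CD 1 and turned to 0.086 with normexp and percentile scaling (adjusted p = 0.326), beside the rise of ALDOC. UGP2 differed by -1.06 and PFKFB1 by -1.23 (adjusted p = 0.0529), and 2 other probes of PFKFB1 passed at -1.83 and -1.78. Insulin and growth factor signalling had a median of -0.29 over 16 genes (adjusted p = 0.522). Within it IGFBP5 differed by 1.31, IGFBP6 by -0.73 and PPARGC1A, a coactivator of mitochondrial genes, by -1.47 (adjusted p = 0.321). SLC2A4, the insulin-responsive glucose transporter, differed by -0.84 (adjusted p = 0.411).

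The cytosolic ribosome list had 28 of 30 genes lower with a median of -0.20, a sign that turned to 0.29 with normexp and percentile scaling (camera adjusted p = 0.0668). It passed as higher in that setting (adjusted p = 0.0128), and as lower without HFHSD 3 (adjusted p = 0.0477) and with the mean of each gene's probes (adjusted p = 0.0383). RPL29 differed by -0.57 and RPL14 by -0.59. All 7 endoplasmic reticulum stress genes were lower, with a median of -0.43 that turned to 0.019 with normexp and percentile scaling (adjusted p = 0.0668), among them DDIT3 (-0.83) and DNAJC3 (-0.56). All 10 proteasome genes were lower, with a median of -0.21 (adjusted p = 0.326) that was -0.070 without CD 1, among them PSMD4 (-0.38). With normexp and percentile scaling the median became 0.28 and PSMD4 became 0.11. Heat shock and chaperones had a median of -0.24, and of 0.25 with normexp and percentile scaling (adjusted p = 0.732), and cell cycle genes of -0.20, and of 0.013 with normexp and quantile normalisation (adjusted p = 0.732). Of 18 genes of oxidative stress and metallothioneins, CAT rose, TXNRD1 fell and 14 were lower (median -0.28, turning to 0.14 with normexp and percentile scaling, adjusted p = 0.326). Fry's test for change in either direction gave an adjusted p of 1.4e-05. HMOX1 differed by -0.99 and TXNIP by 0.64. Among immediate early genes, with a median of -0.17, which turned to 0.17 with normexp and percentile scaling, and a mean of -0.36 (camera adjusted p = 0.639), NR4A3 differed by -2.97 (adjusted p = 0.0501).

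Genes of inflammation and immune cells gave few calls. Of 26 measured genes for inflammatory cytokines and NF-kappaB, 18 were higher, with a median of 0.27 that turned to -0.034 with normexp and percentile scaling (adjusted p = 0.133), and TNFRSF1A fell. TNF differed by 0.83 (adjusted p = 0.593) and IL6 by 1.01 (adjusted p = 0.454). TNF was 1.07 and 0.74 on HFHSD 5 and HFHSD 6, the arrays of slide 1, and -1.70 to -1.10 on the other HFHSD arrays, and it differed by 0.11 with slide as a fixed block and by 0.057 without slide 1. The list of interferon response and antigen presentation had 15 of 28 genes higher and a median of 0.016, which turned to -0.044 with quantile normalisation (adjusted p = 0.137). It passed as higher with slide as a fixed block (median 0.093, adjusted p = 0.0221) and with the mean of each gene's probes (adjusted p = 0.0434). Adjusted over the list alone, SLA-DQB1, PSMB8 (0.90) and GBP2 (1.45, but 0.16 with normexp and percentile scaling and 0.93 without CD 1) passed, and SLA-DQA1 differed by 0.64. All 12 macrophage and myeloid genes were lower, with a median of -0.22 (adjusted p = 0.522), and CD163 differed by -1.13. Lymphocyte genes had a median of 0.36 over 7 genes, which turned to -0.20 with normexp and percentile scaling (adjusted p = 0.231).

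Markers of other cell types did not pass as lists. Fibroblast and fibro-adipogenic progenitor genes had 5 of 6 members higher and a median of 0.33 (adjusted p = 0.0777, exact permutation p = 0.0119, the smallest possible), with LOX, which crosslinks collagen, at 1.40, CD34 at 0.76 and THY1 at 0.51, the last of which turned to -0.34 with normexp and percentile scaling. Extracellular matrix and fibrosis had a median of -0.11, which turned to 0.10 with normexp and percentile scaling, and a mean of 0.070 over 16 genes (camera direction higher, adjusted p = 0.732), with POSTN at 1.46. Smooth muscle and pericyte genes were lower in all 6 members, with a median of -0.39 (adjusted p = 0.274), among them SMTN (-0.80). Endothelial genes had a median of -0.061, a mean of 0.097 and a camera direction of higher (adjusted p = 0.707), and Schwann cell and nerve genes a median of 0.059, a mean of -0.086 and a camera direction of higher (adjusted p = 0.732), with UCHL1 at 0.85, and the medians of both turned, to 0.25 and -0.25, with normexp and percentile scaling.

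**Figure D3:**
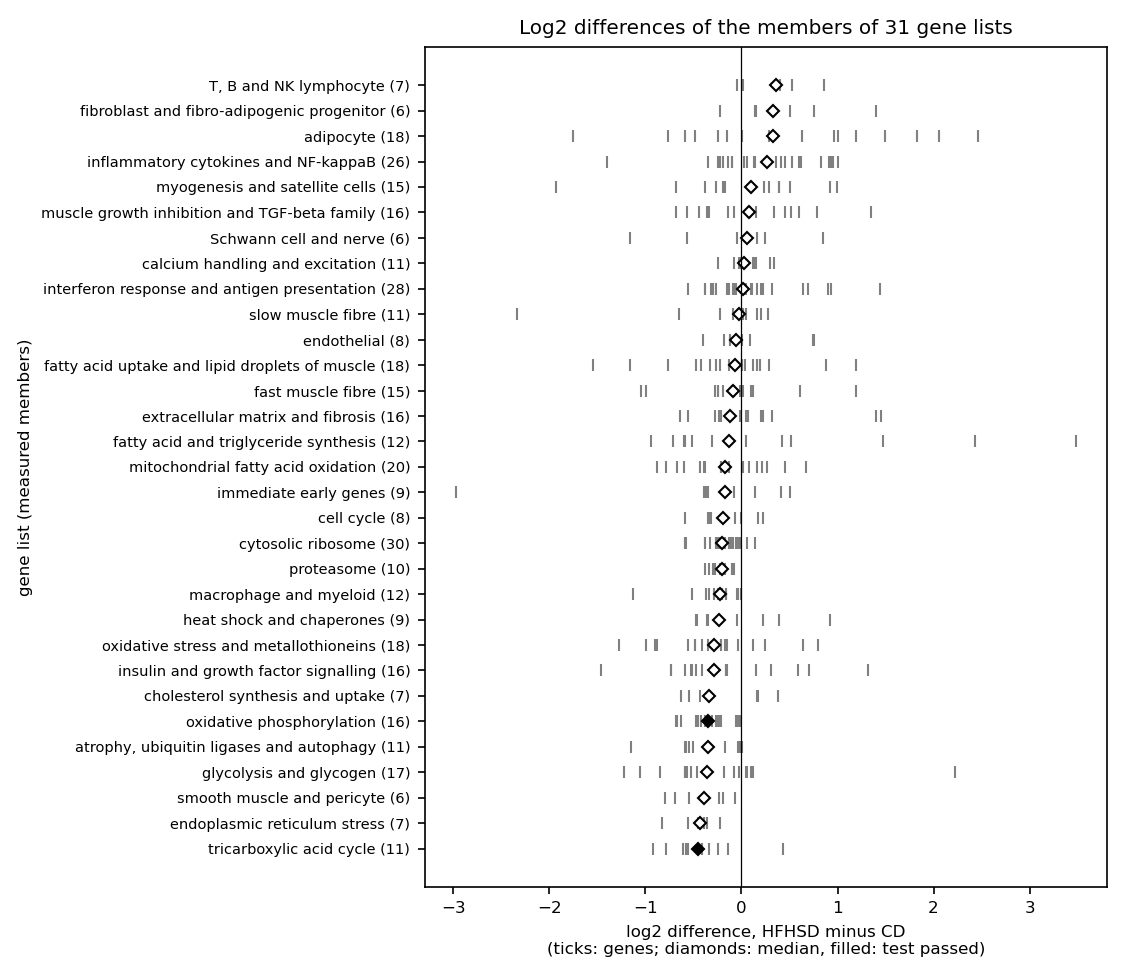
Log2 difference between diets, HFHSD minus CD (x axis), of each measured gene (ticks) in 31 gene lists (y axis, with the number of measured genes), and the median of each list (diamonds, filled where camera passed). The filled medians are those of oxidative phosphorylation (-0.35) and the tricarboxylic acid cycle (-0.45), and both lie under 0, though the former turned to 0.10 with normexp and percentile scaling.

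Arrays separated by slide before diet. Component 1 held 30.5% of the variance and set HFHSD 5 and HFHSD 6, the arrays of slide 1, apart from the others. Component 2 held 20.5% and separated the diets, with HFHSD arrays from 15.0 to 57.0 and CD arrays at -50.7 or lower. Diet accounted for 20.3% of the variance between arrays, and 6 of 84 splits of the arrays gave as large a share (exact permutation p = 0.0714). Slide accounted for 43.0%, a share not separate from that of diet, since slide 1 held only HFHSD arrays. Slide also parts the arrays into 3 groups and diet into 2, so the shares of slide and diet are not directly comparable. No permutation p was computed for the share of slide. The median correlation across probes was 0.974 within CD, 0.961 within HFHSD and 0.960 between diets, and it was 0.968 for arrays of the same slide and 0.959 for arrays of different slides; probes are not independent replicates.

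**Figure D4:**
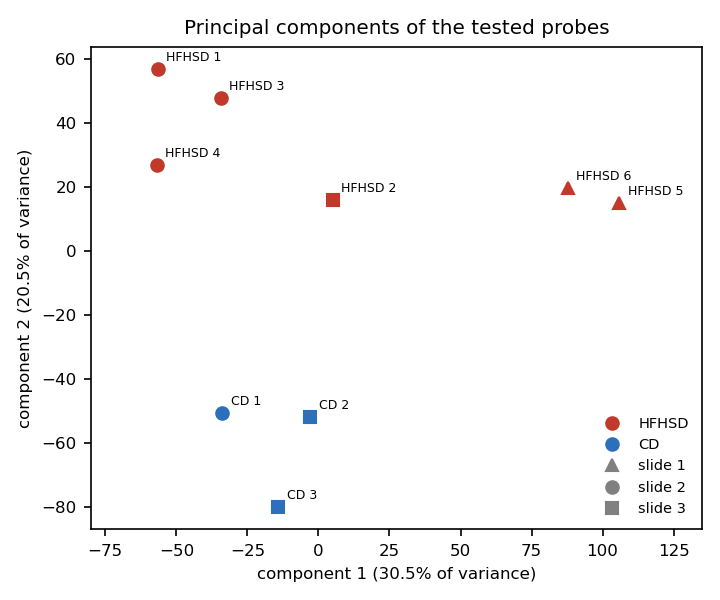
Arrays on principal component 1 (x axis, 30.5% of variance) and component 2 (y axis, 20.5% of variance) of the tested probes, coloured by diet and shaped by slide. The HFHSD arrays lie above 0 and the CD arrays below 0 on component 2.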

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

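The comparison without slide 1 and without CD 1 was chosen after seeing the data, and the predictions for the tests below were written before they were run. Levels of 97 genes and 31 list means were checked for a single HFHSD array far from the other 5, and 6 gene levels stood out, where chance gives about 1 in 20 (6.4 expected). MYOC was 4.99 on HFHSD 3 and 4.24 to 4.47 on the others (gap over range 0.686). NR6A1 was -4.05 on HFHSD 2 and -3.14 to -2.90 on the others (0.790). NCOA3 was -2.94 on HFHSD 1 and -4.14 to -3.77 on the others (0.691). TNFRSF1A was 3.46 on HFHSD 1 and 2.62 to 2.91 on the others (0.648). VCAM1 was 1.44 on HFHSD 5 and 1.99 to 2.25 on the others (0.680). FITM2 was -5.76 on HFHSD 1 and -4.77 to -4.25 on the others (0.655).

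The number of called probes was set against all 84 splits of the arrays into 6 and 3. Only the diet split (1 of 84) gave as many as 344, and the highest of the other splits gave 51, a share of 0.0119, the smallest possible. That highest split set HFHSD 1, HFHSD 3 and HFHSD 4, the HFHSD arrays of slide 2, against the rest. The splits moved arrays freely between slides, so this share does not account for slide. With slide as a fixed block the diet comparison called 84 probes.

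The mean differences of oxidative phosphorylation, the tricarboxylic acid cycle and the cytosolic ribosome were negative, although the ribosome list did not pass (camera adjusted p = 0.0668), and bright genes were lower in general: the median log2 difference was 0.026 in the dimmest of 5 equal groups of genes and -0.18 in the brightest. Each member was therefore compared with the 50 genes nearest in level. The ribosome difference then shrank from -0.20 to -0.053 (exact permutation p = 0.726), consistent with a scaling of abundant transcripts. The tricarboxylic acid cycle kept -0.25 of -0.42 (exact permutation p = 0.0476, not adjusted for the 3 lists), which met the prediction written against scaling as the whole cause. Its median shrank from -0.45 to -0.022 with normexp and percentile scaling, however, so scaling stays open for this list. Oxidative phosphorylation kept -0.19 of -0.35 (exact permutation p = 0.179), too little to decide. An effect of diet on mitochondrial genes stays open for both, as does the slide, since the differences within slide 3 were small. The slide 3 differences rest on a single HFHSD array, HFHSD 2, so they may reflect that animal. HFHSD 2 had the highest oxidative phosphorylation mean of the HFHSD arrays (7.26).

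The adipocyte list differed by a mean of 0.48 without passing (camera adjusted p = 0.0668), and 2 explanations of that difference were weighed. Without CD 1 and without slide 1 the mean was 0.54, so those arrays did not produce the mean difference. CD 1 had the highest list mean of the CD arrays, so leaving it out could only raise the mean difference. The median was 0.30 without those arrays, against 0.33 with all arrays, and the list did not pass with camera (adjusted p = 0.461). If more fat cells lay among the fibres, the other 17 members would follow ADIPOQ across the 6 HFHSD arrays: their median Pearson r was 0.273 (exact permutation p = 0.114, one-sided over all 720 orderings) and their median Spearman rho 0.257 (exact permutation p = 0.0833), and r was 0.199 without the 2 arrays farthest from the median of ADIPOQ. CIDEC (r = 0.971), PPARG (0.967) and PLIN1 (0.931) followed it and PNPLA2 (-0.885), ACSL1 (-0.815) and AQP7 (-0.801), genes that muscle fibres also express, went against it. Fat cells and a change within the fibres cannot be told apart with these arrays, which may hold both.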

How the results depend on the processing

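The percentile over probes detected on all arrays, the comparison without slide 1 and the comparison without slide 1 and CD 1 were chosen after seeing the data; the other settings were not. No paired analysis was possible because the replicate numbers were given in accession order and pair no animals. The authors' deposited value table gave the same 344 probes, since its values equal the scanner values.

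Beside the 344 called probes, which need not be the same probes as those called elsewhere, quantile normalisation called 387 (293 of them shared), normexp with percentile scaling 88 (55 shared), normexp with quantile normalisation 856 (274 shared), no filter on dim probes 66, probes above background on all 9 arrays 736, slide as a fixed block 84 (63 shared), slide as a random block 677, array weights 1205, and a variance trend with a robust prior 612. A log2 difference of at least 1 kept 317, an adjusted p under 0.1 gave 1211, and an unadjusted p under 0.05 with a log2 difference of at least 1 gave 1558. Taking the percentile over probes detected on all arrays gave 488. Without slide 1 there were 57, and without slide 1 and CD 1 there were 16. Fewer arrays entered those fits, and single arrays left out gave 25 to 325, with the lowest counts without CD 3 (25) and CD 1 (32), then HFHSD 3 (75), CD 2 (87), HFHSD 6 (93), HFHSD 2 (99) and HFHSD 5 (161). Of the 344 probes, 318 kept their sign with normexp and percentile scaling, which moved the median of all probes from -0.024 to -0.17. With quantile normalisation all 344 did. All 344 also did with each array left out, but the HFHSD and CD arrays did not overlap for any of these probes. Leaving out 1 array could therefore not turn a sign, so that result is no check. The share of called probes that were higher was 56.4%, and it was 71.6% with normexp and percentile scaling, 38.2% with probes above background on all 9 arrays, 66.2% with the other percentile and 37.5% without slide 1 and CD 1. Without a filter, the median of all probes was -0.20. The cause of these changes was not tested.

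Against 26 called genes, the number of called genes, not all the same, was 29 with quantile normalisation, 64 with the mean of a gene's probes, 8 with normexp and percentile scaling, 99 with normexp and quantile normalisation, 5 without a filter, 86 with probes above background on all 9 arrays, 7 with slide as a fixed block, 67 with slide as a random block, 106 with array weights, 61 with the variance trend and 41 with the other percentile. It was 3 without slide 1 and 1 without slide 1 and CD 1. Single arrays left out gave 2 to 32, with 2 without CD 1 or CD 3, 5 without HFHSD 3, 6 without HFHSD 2, 8 without HFHSD 6 or CD 2 and 15 without HFHSD 5. MUL1 passed in all 23 alternatives, with -4.85 to -3.13, MYOC in 22 of 23, SLC25A6 in 19 and EPHX1 in 18.

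Against 2 called lists, 0 lists passed with quantile normalisation, with probes above background on all 9 arrays, with slide as a random block, with array weights, with the other percentile, without slide 1, without slide 1 and CD 1, with an estimated correlation and with the exact permutation test. With slide as a fixed block 1 list passed, interferon response and antigen presentation. With normexp and percentile scaling 4 passed, all higher: myogenesis and satellite cells, cytosolic ribosome, calcium handling and excitation, and fast muscle fibre. Neither of the 2 called lists was among these. In that setting the medians of bright lists rose, as for cytosolic ribosome (-0.20 to 0.29), oxidative phosphorylation (-0.35 to 0.10) and fast muscle fibre (-0.087 to 0.37). Medians of dim lists fell, as for lymphocyte (0.36 to -0.20) and inflammatory cytokines and NF-kappaB (0.27 to -0.034). The calls and turned signs of that setting are thus not independent of each other. Without a filter 4 passed and with the mean of a gene's probes 5, and each of these held both called lists. Single arrays left out gave 0 to 5: 0 without HFHSD 1, HFHSD 5, HFHSD 6, CD 1 or CD 3, 5 without HFHSD 3, 4 without CD 2 and 3 without HFHSD 4. CD 1, on which 36.8% of probes were well above background, limits what can be measured for dim probes. Diet accounted for 20.3% of the variance between arrays, and for 21.4% with quantile normalisation.

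Among genes that kept their sign, normexp and percentile scaling shrank these to under 0.5 of their difference: METTL11B (0.34), APOE (0.40), BMPR1B (0.73), KCNN3 (0.49), TIGD4 (0.55), NR6A1 (-0.82), NCOA3 (-0.76), DGAT2 (0.37), PNPLA3 (1.34), CIDEC (0.47), LEP (0.092), MSTN (0.37), MYOD1 (-0.82), FITM2 (-0.71), FBXO32 (-0.068) and UCP3 (-0.29). It also did so for PDK4 (-0.35), SLC2A4 (-0.35), TNF (0.40), IL6 (0.19), CS (-0.30), MDH2 (-0.15), COX5B (-0.19), ATP5G1 (-0.26), COX7A1 (-0.042), RPL29 (-0.13), RPL14 (-0.090), IGFBP6 (-0.18), GBP2 (0.16), SMTN (-0.29), POSTN (0.20) and KDM5C (-0.020).

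Leaving out CD 1 alone shrank list medians for glycolysis and glycogen (-0.17), proteasome (-0.070), insulin and growth factor signalling (-0.16), atrophy (-0.23), cholesterol synthesis and uptake (-0.21), oxidative stress and metallothioneins (-0.12), immediate early genes (-0.096), cell cycle (-0.10) and macrophage and myeloid (-0.067). With slide as a fixed block the medians were 0.10 for inflammatory cytokines and NF-kappaB, 0.12 for lymphocyte, -0.20 for smooth muscle and pericyte, -0.11 for cell cycle and -0.050 for mitochondrial fatty acid oxidation.

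With normexp and percentile scaling, the sign turned for fatty acid and triglyceride synthesis (0.18), fatty acid uptake and lipid droplets of muscle (0.16), mitochondrial fatty acid oxidation (0.14), oxidative phosphorylation (0.10), glycolysis and glycogen (0.086), muscle growth inhibition and TGF-beta family (-0.13), atrophy (0.079), proteasome (0.28) and cytosolic ribosome (0.29). In that setting it also turned for inflammatory cytokines and NF-kappaB (-0.034), extracellular matrix and fibrosis (0.10), endoplasmic reticulum stress (0.019), heat shock and chaperones (0.25), oxidative stress and metallothioneins (0.14), immediate early genes (0.17), slow muscle fibre (0.43), fast muscle fibre (0.37) and lymphocyte (-0.20). In that setting it also turned for endothelial (0.25), Schwann cell and nerve (-0.25), DMP1 (-0.019), PLIN1 (-0.16), MYOG (0.0071), MYH7 (0.33), SUCLG1 (0.0095), THY1 (-0.34) and PSMD4 (0.11). In that setting it also turned for SMAD2 (-0.13). With normexp and quantile normalisation, the sign turned for fatty acid uptake and lipid droplets of muscle (0.0077), cell cycle (0.013), slow muscle fibre (0.093), endothelial (0.012) and THY1 (-0.10). With probes above background on all 9 arrays, the sign turned for fatty acid uptake and lipid droplets of muscle (0.0073), muscle growth inhibition and TGF-beta family (-0.14) and endothelial (0.00086). With slide as a fixed block, the sign turned for fatty acid uptake and lipid droplets of muscle (0.18), slow muscle fibre (0.36), endothelial (0.27), Schwann cell and nerve (-0.22) and MYH1 (-0.11). With slide as a random block, the sign turned for fatty acid uptake and lipid droplets of muscle (0.068), interferon response and antigen presentation (-0.017), slow muscle fibre (0.17), endothelial (0.12), Schwann cell and nerve (-0.040) and MYH1 (-0.029). With array weights, the sign turned for fatty acid uptake and lipid droplets of muscle (0.0025), slow muscle fibre (0.12), Schwann cell and nerve (-0.12) and MYH1 (-0.12). With the percentile taken over probes above background on all 9 arrays, the sign turned for fatty acid uptake and lipid droplets of muscle (0.023), slow muscle fibre (0.065), endothelial (0.026) and DDX3X (0.0077). Without slide 1, the sign turned for fatty acid uptake and lipid droplets of muscle (0.046), slow muscle fibre (0.024), endothelial (0.17), Schwann cell and nerve (-0.34), MYH1 (-0.25) and DDX3X (0.016). Without slide 1 and CD 1, the sign turned for fatty acid uptake and lipid droplets of muscle (0.085), muscle growth inhibition and TGF-beta family (-0.046), extracellular matrix and fibrosis (0.11), slow muscle fibre (0.021), fast muscle fibre (0.019), macrophage and myeloid (0.081), Schwann cell and nerve (-0.29), MYH1 (-0.36) and DDX3X (0.057). With quantile normalisation, the sign turned for interferon response and antigen presentation (-0.044), slow muscle fibre (0.076), fast muscle fibre (0.030) and endothelial (0.020). Without a filter on dim probes, the sign turned for interferon response and antigen presentation (-0.022), lymphocyte (-0.048) and Schwann cell and nerve (-0.042). With the mean of a gene's probes, the sign turned for slow muscle fibre (0.084), endothelial (0.087), MYH7 (0.0065) and MYH1 (-0.10). With single arrays left out, the ranges that crossed 0 ran for fatty acid uptake and lipid droplets of muscle from -0.16 to 0.016, myogenesis and satellite cells from -0.059 to 0.17, interferon response and antigen presentation from -0.059 to 0.11, extracellular matrix and fibrosis from -0.17 to 0.0055, calcium handling and excitation from -0.063 to 0.20 and slow muscle fibre from -0.26 to 0.25. They also ran for fast muscle fibre from -0.16 to 0.024, endothelial from -0.16 to 0.080, Schwann cell and nerve from -0.087 to 0.28, CD36 from -0.18 to 0.34, LPL from -0.16 to 0.36 and IGF2 from -0.059 to 0.35. They also ran for MYH1 from -0.11 to 0.12 and DDX3X from -0.26 to 0.060.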

Other observations

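The count over splits with at least 2 arrays on each side was chosen only after the count over all splits was seen, and the other test here was not. The largest differences between the diets were in probes without a gene name, and these probes were chosen after their values were seen. Probe A_72_P213291 was 5.54 ± 0.18 (SD, n = 3) in CD and not well above background on any HFHSD array, at least 885-fold higher in CD (adjusted p = 1.4e-07). Probe A_72_P151441 was 0.77 ± 0.19 (SD, n = 3) in CD and also not well above background in HFHSD, at least 32.5-fold higher in CD (adjusted p = 7.2e-06). In all, 4 probes were well above background on every CD array and on none of the HFHSD arrays with a gap of at least 2 in log2, and 0 probes showed the opposite. The CD arrays lie on slides 2 and 3, which also hold HFHSD arrays.

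A hypothesis is that the sexes were not spread evenly over the diets, since the labels name both sexes and give none per animal. It was predicted, before the splits were counted, that the diet split would then hold more such probes than any other way to part the 9 arrays in 2. The diet split held 4, while 1 array against the other 8 held up to 89, and among other splits with at least 2 arrays on each side the most was 6. Single arrays held many such probes whichever diet they came from, and the prediction follows only if sex matched diet exactly, so these counts do not weigh the hypothesis that the sex of the animals differed between the diets. The 3 X-linked genes EIF1AX, DDX3X and KDM5C were chosen after their values were seen and were in no tested list, with EIF1AX at 0.95 (adjusted p = 0.0653), DDX3X at -0.079 and KDM5C at -0.42. KDM5C shrank to -0.020 with normexp and percentile scaling. Sex, genotype and diet stay open for these 4 probes, and sex itself was not tested because no array could be assigned one.

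Several genes passed only by a probe other than the brightest, and they were chosen after their values were seen. TUSC5, a gene of fat cells in the adipocyte list, had a probe at 3.26 (adjusted p = 0.0286) while its brightest probe was at 0.33. VEGFA, an inducer of blood vessel growth, had a probe at -2.33 (adjusted p = 0.0452) and its brightest probe at -2.39 (adjusted p = 0.0631). A probe of CYCS, which encodes cytochrome c and is in the oxidative phosphorylation list, was at -1.30 (adjusted p = 0.0340) with its brightest probe at -0.42. OAT, an enzyme of ornithine metabolism, had a probe at 1.09 (adjusted p = 0.0416) and its brightest at 1.24 (adjusted p = 0.0899).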
